A study of Homo sapiens with 18 samples.

How the data were processed

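Expression was measured by RNA sequencing of total RNA from LNCaP cells grown in RPMI medium with 10% fetal bovine serum. Cells were treated for 24 h with DMSO or 10 uM of UPF1069, olaparib or veliparib, or transfected for 72 h with the control siRNA siNC or with 1 of 4 siRNAs, siPARP1_A, siPARP1_B, siPARP2_A and siPARP2_B. RNA was extracted with the RNeasy kit and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The 18 libraries, 8 in the inhibitor table and 10 in the siRNA table, make 9 groups with 2 libraries per group. Groups were taken from the labels alone.

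The values of the inhibitor table are counts per M reads (CPM): as deposited by the authors, each value is a whole number of reads divided by a library size scaled by a factor of 0.9906 to 1.0094, as read from the step between values. The siRNA table holds a normalised signal: as deposited by the authors, each value is a whole number of reads per M of a library size scaled by a factor of 0.891 to 1.0366, so its column sums run from 964646.5 to 1122366.8 and it is no plain CPM. Reads were recovered by dividing by the step of each library, and 100% of the values above 0 lay within 0.01 of a whole read. The submitters' processing notes name bcl2fastq 2.18, TopHat2 2.1.0, HTSeq 0.6.1, edgeR 3.12.0 and the genome build hg19, without their roles. The tables hold 21391 and 18350 features, 17714 of them in both, and no column was left unused. A symbol was missing for 4941 and 3517 features; a GENCODE table for another build was searched by identifier, and 2862 and 1776 features still had the identifier alone. Recovered depth was 26.43 to 35.7 M reads per inhibitor library and 15.45 to 18.62 M per siRNA library, so that 3 reads make 0.0841 to 0.113 CPM and 0.169 to 0.207 normalised reads per M. Coordinates were not used.

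The design had been written for read counts, with edgeR's quasi-likelihood test, and with limma as the test for values that are not counts. Since the tables hold normalised values, the main test was limma's trend method on log2(value + 1) of the deposited values, 2-sided, for genes with a mean of at least 1 over the table: 13337 in the inhibitor and 12701 in the siRNA table, 12004 of them in both. All groups of a table entered 1 fit without further covariates, with 4 and 5 residual degrees of freedom and prior degrees of freedom of 17.6 and 19. Benjamini-Hochberg adjustment ran over all genes of a comparison, with a threshold of 0.05. The edgeR quasi-likelihood test and DESeq2 on the recovered reads were alternatives. The tables were normalised apart and were tested apart.

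Each inhibitor was compared with DMSO and with each other inhibitor, each siRNA with siNC, the sequences of a target with each other, and the mean of the siPARP2 with the mean of the siPARP1 sequences. A change with both sequences of a target needed an adjusted p below 0.05 and the same sign in each. The median standard error of a log2 fold change was 0.062 in the inhibitor and 0.094 in the siRNA comparisons with a control. The method was tested on simulated data with the noise and depth of a 2 against 2 comparison. In the inhibitor table it recovered 54, 86, 100 and 100% of genes with a true log2 change of 0.25, 0.5, 1 and 2. It called 18 of 13080 unchanged genes beside 166 changed ones. In the siRNA table it recovered 22, 64, 84 and 100% and called 9 of 12450 unchanged genes beside 134 changed ones. In this simulation unchanged genes thus made up a larger share of the calls than the threshold of 0.05 aims at. The simulation gave all groups of a table the same spread per gene, whereas the measured noise differed between groups, as given below. Its numbers of false calls therefore need not hold for these data. It also changed few genes, at most 50 of each size, whereas 24.3% of genes were called with UPF1069 and 49.4% with siPARP2_A. The p value needed to pass therefore differed, and the shares recovered need not hold either.

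The chi-square per gene between replicates, which is 1 for counting noise alone, was 1.57 for DMSO, 1.28 for UPF1069, 1.99 for olaparib, 5.64 for veliparib, 7.7 for siNC, 2.54 and 3.81 for siPARP1_A and siPARP1_B, and 3.6 and 5.94 for siPARP2_A and siPARP2_B.

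The 23 gene lists, the named-gene rule, the comparisons and most alternatives were fixed before the data were examined. The lists were androgen-induced genes, androgen-repressed genes, prostate luminal transcription factors, the poly(ADP-ribose) polymerase family, p53 targets, DNA replication and S phase, mitosis and G2/M, homologous recombination and Fanconi genes, base excision and single-strand break repair, interferon-stimulated genes, NF-kB and inflammatory cytokine targets, aryl hydrocarbon receptor targets, the integrated stress and unfolded protein responses, cholesterol biosynthesis, fatty acid synthesis, NRF2 targets, glycolysis and hypoxia, the epithelial-mesenchymal transition, and markers of neuroendocrine, basal, luminal, stromal, and immune and endothelial cells. Lists share some genes, such as FEN1. NDRG1 of the glycolysis and hypoxia list and ACSL3 of the fatty acid list are also in the androgen-induced list. They were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, if at least 5 members were tested. The correlation estimated from the data and the fry test were alternatives, and an estimate from so few residual degrees of freedom is itself uncertain. With an estimated correlation, camera also takes its degrees of freedom from the fit (4 and 5) rather than from the number of genes. A call can thus be lost with it although the members are not correlated.

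Genes named were the 8 most raised and 8 most lowered for each inhibitor and, with both sequences, for each knockdown, 6 and 6 for siPARP2 against siPARP1, 4 and 4 for each pair of inhibitors, up to 4 top members of each called list, and a fixed set with PARP1, PARP2, FOXA1, KLK3, KLK2, TMPRSS2, FKBP5, CDKN1A and CYP1A1. Some genes that this rule names are not reported here, and they stayed in the gene lists and in the counts of genes. Ranked genes had an adjusted p below 0.05, a mean log2 value of at least 1, a symbol, and every treated library beyond every control library. CYP1A1 was below the filter in the inhibitor table and is reported for the siRNA table only.

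The genes raised and lowered by each inhibitor were tested as sets with camera in each knockdown, over 12275 genes with an inhibitor test and a siRNA value. The p values of these sets were adjusted over the 12 tests. The design did not fix this adjustment, which was chosen after the unadjusted values had been seen.

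Alternatives fixed beforehand were RLE size factors, DESeq2, no filter on low values, a pseudocount of 0.1, a fit of the compared groups alone, a replicate block, each library left out in turn, sets with an absolute log2 fold change of at least 1, an estimated correlation and fry. Alternatives chosen after the data had been seen were edgeR on recovered reads, a threshold of 1 on the absolute log2 fold change, a correction of each library for GC content and transcript length, 1 value per sequence, a comparison without siPARP2_B, each sequence alone, and the mean of both sequences. Without 1 library, the lone library of its group is assumed to vary like the other groups. For comparisons that share a control, 100 simulations of unchanged groups gave the correlation and the number of common calls to be had with no effect. With no effect the shared control alone sets r near 0.5. An r below that value therefore does not show less agreement, and covariances are given beside it. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.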

Results

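Gene expression was measured by RNA sequencing in 18 libraries of LNCaP, an androgen-responsive human prostate cancer cell line. The libraries fall into 9 groups with 2 libraries per group, which the series calls biological duplicates. In the inhibitor experiment, cells received the solvent DMSO or 10 uM of UPF1069, olaparib or veliparib for 24 h. In the knockdown experiment, cells were transfected for 72 h with a control siRNA (siNC) or with an siRNA against PARP1 or PARP2, and sequences A and B were used against each target. PARP1 and PARP2 are nuclear enzymes that attach chains of ADP-ribose to proteins at DNA breaks and on chromatin. Olaparib and veliparib are inhibitors of both enzymes, and UPF1069 is a compound sold as an inhibitor of PARP2. The series asks what loss or inhibition of PARP1 or PARP2 does to the transcripts of prostate cancer cells. Group labels were taken as given, and no measured transcript identifies a compound.

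The inhibitor libraries held 26.4 to 35.7 M recovered reads and the siRNA libraries 15.45 to 18.62 M. A count of 3 reads corresponded to 0.0841 to 0.113 CPM in the inhibitor libraries and to 0.169 to 0.207 normalised reads per M in the siRNA libraries, and these floors cover counting error only, while the intervals given come from limma and its variance between libraries. All fold changes are on the scale of log2(value + 1), which understates the change of weakly expressed genes. Adjusted p values of genes come from limma, those of gene lists from camera, both with Benjamini-Hochberg adjustment. Rankings of genes cover those that passed with a symbol, a mean log2 value of at least 1 and every library of one side beyond every library of the other.

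UPF1069 raised the targets of p53 and lowered the genes of mitosis. With UPF1069, 30 of 31 measured p53 targets rose and 28 of 30 mitotic genes fell, while 1 mitotic gene rose. The genes that androgen induces moved little: 17 of 43 fell and 4 rose, with a median log2 fold change of -0.10. Genes of the unfolded protein and amino acid stress responses fell as a group, as did genes of glycolysis and hypoxia. Both lists also fell with veliparib, and the glycolysis list with olaparib, against the same DMSO libraries, as given below.

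CDKN1A, which encodes the cell cycle inhibitor p21, rose from 311 ± 1.22 CPM in DMSO to 1494 ± 3.17 CPM with UPF1069 (SD, n = 2; log2 fold change 2.26, SE 0.03, adjusted p = 2.78e-22). TP53I3, an oxidoreductase gene activated by p53, rose from 7.38 ± 0.124 to 56.1 ± 0.0375 CPM, a log2 fold change of 2.77. FDXR, the mitochondrial ferredoxin reductase, rose by 1.49 and GDF15, a secreted stress cytokine, by 1.48. Among the most raised genes outside the p53 list were CEL, a lipase gene, at 2.07, FAXDC2, a sterol-metabolism gene, at 1.84, APOBEC3H, a cytidine deaminase, at 1.56, and SERPINB5, the epithelial serpin maspin, at 1.52. PLK1, the kinase that drives mitotic entry, fell from 118.5 ± 1.23 to 51.7 ± 1.93 CPM, a log2 fold change of -1.18. CDC20, an activator of the anaphase-promoting complex, changed by -0.997 and KIF20A, a kinesin of cytokinesis, by -0.95. The largest fall was that of DHRS2, a short-chain dehydrogenase, at -1.55, followed by PLK1 and by TM4SF1, a membrane protein gene, at -1.16. The other genes with the largest falls were STC1, a secreted glycoprotein, at -1.03, PIF1, a DNA helicase, at -0.94, and HIST1H2BJ at -1.13, whose near-identical copies make its reads uncertain.

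Of the stress-response list, 20 of 28 genes fell and 2 rose (median -0.30), led by PSAT1 of serine synthesis at -0.62, the pseudokinase TRIB3 at -0.65, the cystine transporter SLC7A11 at -0.68 and asparagine synthetase ASNS at -0.46. Of the glycolysis and hypoxia list, 13 of 19 fell (median -0.19), with lactate dehydrogenase LDHA at -0.40 and PGK1 at -0.29. Of the lipid synthesis lists, 14 of 24 cholesterol genes fell and 1 rose, with HMGCS1 at -0.33, and 9 of 15 fatty acid genes fell and 1 rose, with ACSL3 at -0.35. Among the interferon-stimulated genes 5 of 24 rose, OASL by 0.46, and among the androgen-repressed genes 7 of 17 rose and 2 fell, with ACKR3 at 0.42 and UGT2B17, which shares reads with its paralogs, at 0.41. Of the androgen-induced genes, KLK3, which encodes the prostate-specific antigen, went from 1437 ± 10.8 to 1257 ± 9.52 CPM (-0.19, adjusted p = 0.00102), TSC22D3 changed by -0.41, CHRNA2 by -0.60 and FKBP5 by -0.22. FOXA1 (-0.00) did not pass the threshold. PARP2 changed by -0.22, a call that ended without UPF1069 replicate 1 (adjusted p = 0.0537). The calls of PARP1 (-0.14), KLK2 (-0.14) and TMPRSS2 (0.12) ended without any 1 of the DMSO or UPF1069 libraries (adjusted p between 0.052 and 0.301), and that of KLK2 also with RLE size factors (0.0557) and DESeq2 (0.0518).

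The camera test called the p53 list (adjusted p = 7.46e-55), the mitotic list (3.54e-36), the stress-response list (2.32e-13) and the glycolysis list (1.17e-06), and these calls held with an estimated correlation, with adjusted p = 0.00105, 0.00955, 0.00955 and 0.0236. Adjusted over the list alone, 30 p53 targets rose, 29 mitotic genes fell and 1 rose, 22 stress-response genes fell and 2 rose, and 13 glycolysis genes fell and 1 rose. The calls of the cholesterol, fatty acid, androgen-induced, interferon and androgen-repressed lists (0.000282, 0.00162, 0.00356, 0.0109 and 0.0152) were lost with an estimated correlation (0.0707, 0.0707, 0.0824, 0.0824 and 0.364), and without UPF1069 replicate 2 the interferon and androgen-repressed calls ended as well (0.0535 and 0.079, with the androgen-repressed median at -0.01), the androgen-repressed call also with fry (0.103). The lists of DNA replication (7 fell and 4 rose of 33), homologous recombination (4 rose and 1 fell of 32), base excision repair (3 fell and 2 rose of 23) and targets of the aryl hydrocarbon receptor (2 rose and 1 fell of 5) were not called, with adjusted p of 0.253, 0.397, 0.714 and 0.923. In all, 1372 of 13337 genes rose and 1873 fell, of which 29 rose and 6 fell by at least 2-fold. Recovered reads tested with edgeR gave 3244 genes, 1698 raised and 1546 lowered. The limma count of 3245 fell without any 1 of the compared libraries and rose without either veliparib library. With only the groups compared it was 5041, so including the other compounds in the fit lowered it.

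Olaparib lowered the androgen-induced genes and the genes of DNA replication and mitosis, and left the p53 targets without a common direction. With olaparib, 40 of 43 measured androgen-induced genes fell and 2 rose, all 30 mitotic genes fell, and 32 of 33 replication genes fell. Of the p53 targets, 9 of 31 rose and 11 fell.

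KLK3 fell from 1437 ± 10.8 CPM in DMSO to 179.6 ± 1.44 CPM with olaparib (SD, n = 2; log2 fold change -2.99, SE 0.04, adjusted p = 5.94e-24). Its neighbour in the kallikrein family, KLK2, fell from 265 ± 9.56 to 10.4 ± 0.731 CPM (-4.55), and TMPRSS2, a membrane serine protease, from 493 ± 0.147 to 70.8 ± 0.634 CPM (-2.78). FKBP5, an immunophilin gene induced by steroids, changed by -1.72. The other genes with the largest falls were CHRNA2, an acetylcholine receptor subunit, at -4.13, the cold-sensing channel TRPM8 at -3.90, ADAM7 at -3.52, TM4SF1 at -3.14, the glycosyltransferase ST6GALNAC1 at -2.97, and TARP at -3.08, a T cell receptor locus whose reads overlap neighbouring genes. FOXA1, a pioneer factor that opens chromatin, rose by 0.29. PARP1 changed by -0.31 and PARP2 by -0.55. CDKN1A was at 331 ± 1.91 CPM (0.09), a call that ended without any 1 of the DMSO, UPF1069 or olaparib libraries (0.0655 to 0.148) and without a filter on low values (0.0557).

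The most raised genes were ID1 and ID3, inhibitors of basic helix-loop-helix factors, at 2.34 and 1.89, the neuropeptide gene NTS at 2.24, the growth factor carrier IGFBP3 at 2.11, the mannosidase MAN1A1 at 1.95, CSMD1, from 44.8 ± 1.04 to 159 ± 6.24 CPM, the phospholipase PLD1 at 1.77 and ACTRT3 at 1.72. ID1 went from 7.48 ± 0.134 to 41.9 ± 0.304 CPM. Of the androgen-repressed genes, 9 of 17 rose and 5 fell, with the adaptor GRB10 at 1.30, dopa decarboxylase DDC at 1.10 and CAMK2N1 at 0.97. MKI67, the proliferation marker, changed by -1.57, NUSAP1 by -0.95, the ribonucleotide reductase subunit RRM2 by -1.05, the helicase subunit MCM4 by -0.91 and the flap nuclease FEN1 by -0.91. Among genes of homologous recombination and the Fanconi pathway, 26 of 32 fell and 1 rose, with FANCI at -0.68 and RAD54L at -1.02. Of the base excision genes 11 of 23 fell and 2 rose, APEX2 by -0.52. Targets of NRF2, the regulator of the oxidative stress response, rose in 13 of 17 cases and fell in 1, with NQO1 at 0.68 and the ferritin genes FTL and FTH1 at 0.51 and 0.46. Of the glycolysis and hypoxia list 13 of 19 fell and 2 rose, with NDRG1, which is also in the androgen-induced list, at -0.89 and HK2 at -0.94. Of the fatty acid list 9 of 15 fell and 4 rose, with the elongases ELOVL7 and ELOVL5 at -1.94 and -1.30, and of the epithelial-mesenchymal list 6 of 9 fell, with THBS1 at -0.93 and FN1 at -0.57.

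The androgen-induced list had a median of -1.14 (camera adjusted p = 4.53e-33), the mitotic list -0.81 (1.27e-24), the replication list -0.74 (4.08e-22) and the glycolysis list -0.30 (6.68e-05), and with an estimated correlation these had adjusted p = 0.00327, 0.02, 0.00327 and 0.0469. The calls of the homologous recombination list (7.47e-09), the NRF2 list (4.96e-05), the epithelial-mesenchymal list (0.00206), the fatty acid list (0.0194), the base excision list (0.031) and the androgen-repressed list (0.031) were lost with an estimated correlation, with adjusted p = 0.0789, 0.0801, 0.0789, 0.117, 0.117 and 0.372. Adjusted over the list alone, 40 androgen-induced, 30 mitotic, 33 replication and 13 glycolysis genes fell, and 2 androgen-induced and 2 glycolysis genes rose. The p53 list was not called (median -0.02, adjusted p = 0.775), nor was the list of inflammatory NF-kB targets (6 fell and 1 rose of 10, adjusted p = 0.118). Of 13337 genes, 3435 rose and 3569 fell, 72 and 176 of them by at least 2-fold, and edgeR on recovered reads called 7628.

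**Figure D1:**
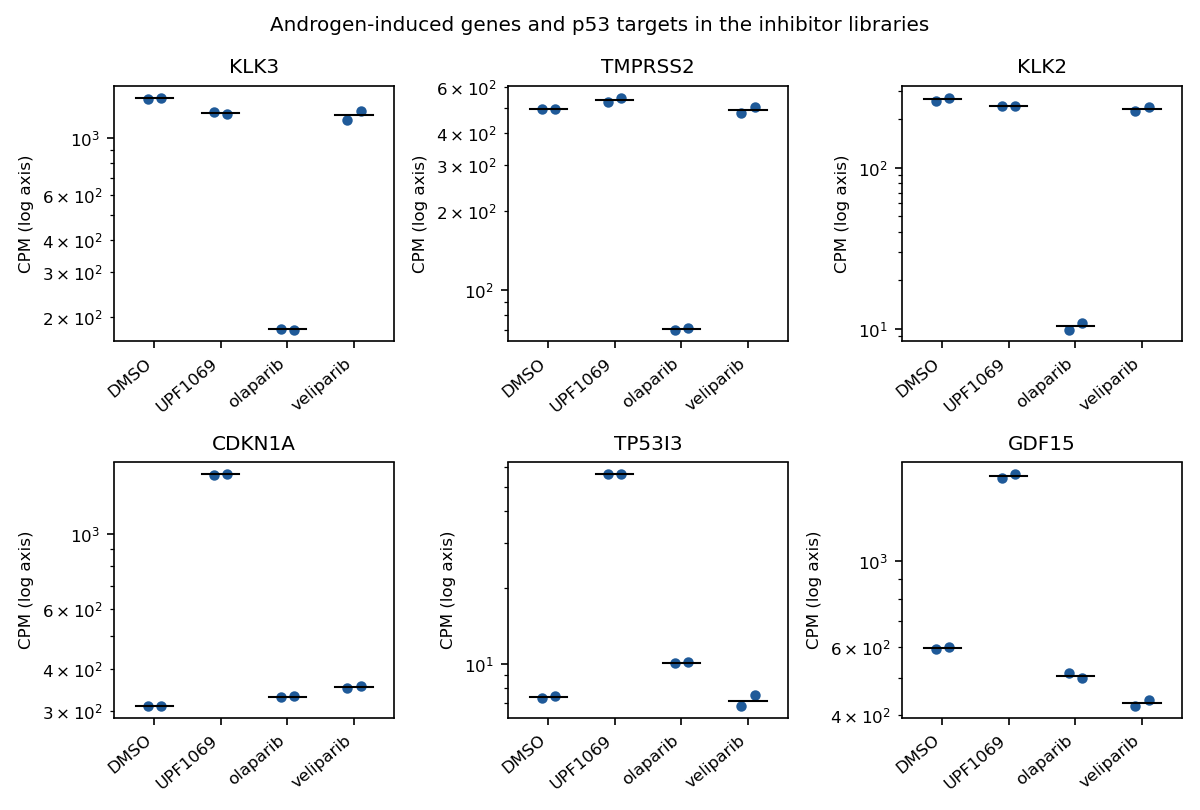
CPM on log axes in each inhibitor library (points) with group means (bars) for KLK3, TMPRSS2, KLK2, CDKN1A, TP53I3 and GDF15. KLK3 was at 179.6 CPM with olaparib against 1437 CPM in DMSO, and CDKN1A at 1494 CPM with UPF1069 against 311 CPM.

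Veliparib changed many genes by a small amount. By at least 2-fold 9 genes rose and 3 fell, and of the raised ones 5 were structural RNAs, which carry no poly(A) tail, 1 was a pseudogene of such an RNA and 3 had no symbol. Genes of glycolysis and of the stress responses fell, and p53 targets rose slightly, a list call that was lost with an estimated correlation (adjusted p = 0.169). The androgen-induced genes had no common direction, with 8 of 43 raised and 10 lowered.

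RNA28S5, a ribosomal RNA with many near-identical copies, rose from 117 ± 2.34 to 774 ± 43.6 CPM with veliparib (SD, n = 2; log2 fold change 2.72, SE 0.15, adjusted p = 4.01e-11). RN7SL1, the RNA of the signal recognition particle, rose by 2.47, the small nuclear RNA RN7SK by 1.49, the RNA of the processing ribonuclease RMRP by 1.07 and SNORA76C by 1.26, while RNA5-8SP6 and EEF1A1P19, at 1.25 and 0.97, are pseudogenes whose reads are uncertain. The developmental gene MAB21L3 rose by 0.92. NDUFA4L2, a mitochondrial gene induced by hypoxia, fell from 55.7 ± 1.14 to 21.7 ± 0.087 CPM (-1.32). The other large falls were those of PCSK1N at -1.01, LRRC26 at -0.997, the phosphatase PDXP at -0.94, TGFBR3L at -0.93, the deformylase PDF at -0.91, TMEM238 at -0.87 and the pseudogene UQCRFS1P1 at -1.05. Of the glycolysis and hypoxia list 14 of 19 fell, with NDRG1 at -0.45, aldolase ALDOA at -0.46 and the glucose transporter SLC2A1 at -0.43. Of the stress-response list 21 of 28 fell and 2 rose, with DDIT4 at -0.67, CEBPB at -0.73 and CHAC1 at -0.82. Of the p53 targets 17 of 31 rose and 4 fell, with MDM2 at 0.38 and RPS27L at 0.33, while GDF15 changed by -0.47. Of the homologous recombination genes 11 of 32 rose and 3 fell, RAD50 by 0.43. KLK3 changed by -0.23 and CDKN1A by 0.18. FOXA1 changed by -0.25, FKBP5 by 0.18 and KLK2 by -0.19, calls that ended after correction for GC content and length (adjusted p = 0.13, 0.0588 and 0.0774), and the KLK2 call also ended without DMSO replicate 2 (0.0648). PARP1 changed by 0.12, a call that ended without DMSO replicate 1 or 2 (0.0589 and 0.0634) and with only the groups compared (0.0554). PARP2 (-0.06) and TMPRSS2 (-0.01) did not pass.

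The glycolysis list had a median of -0.29 and the stress-response list of -0.21, each with a camera adjusted p = 4.66e-07 and, with an estimated correlation, 0.0376. The p53 list (median 0.16, adjusted p = 0.0168) and the homologous recombination list (0.12, adjusted p = 0.0357) were lost with an estimated correlation, with adjusted p = 0.169 and 0.504. The homologous recombination call also ended without DMSO replicate 1 (0.0651), without veliparib replicate 1 (0.11) and after correction for GC content and length (0.326). Adjusted over the list alone, 15 glycolysis genes fell, 21 stress-response genes fell and 2 rose, and 17 p53 targets rose and 5 fell. The androgen-induced list was not called (adjusted p = 0.857). Of 13337 genes, 2291 rose and 3096 fell, and edgeR called 5425 on recovered reads, 2656 raised and 2769 lowered. Across genes, which are not independent replicates, the veliparib fold changes followed GC content with a Spearman's rho of -0.698, against 0.116 for UPF1069 and -0.112 for olaparib. After correction for GC content and length 3273 genes were called, 2642 of them called before in the same direction, and without DMSO replicate 1 the uncorrected count was 3560.

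The compounds differed from each other in the androgen, p53, mitotic and replication genes, though not each pair in each list. Between UPF1069 and olaparib, 37 of 43 androgen-induced genes were higher with UPF1069 and 1 was lower (median 1.09, adjusted p = 1.66e-33, and 0.00258 with an estimated correlation), and 28 of 31 p53 targets were higher and 2 lower (median 0.89, 1.13e-20 and 0.00258). KLK2 was higher by 4.41, TRPM8 by 3.82, CHRNA2 by 3.53, ADAM7 by 3.50, KLK3 by 2.80 and CDKN1A by 2.17, while ID1 differed by -2.70, IGFBP3 by -2.01, DHRS2 by -1.97 and PLD1 by -1.87. Of the replication genes 32 of 33 were higher with UPF1069 (median 0.68, 3.92e-23 and 0.00258). Lists called only with the preset correlation were those of mitosis, homologous recombination, base excision, interferon, NF-kB, the epithelial-mesenchymal transition, the stress responses and NRF2, whose adjusted p with an estimated correlation was 0.07, 0.0654, 0.119, 0.07, 0.119, 0.0654, 0.0615 and 0.07. Of the NF-kB targets 6 of 10 were higher with UPF1069, NFKB2 by 0.57.

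Between UPF1069 and veliparib, 30 of 31 p53 targets were higher with UPF1069 (median 0.62, adjusted p = 1.09e-21, and 0.0069 with an estimated correlation) and 29 of 30 mitotic genes were lower (median -0.63, 4.06e-22 and 0.0359). TP53I3 was higher by 2.81, CDKN1A by 2.08, CEL by 2.02 and GDF15 by 1.95, while RNA28S5 differed by -1.99, RN7SL1 by -1.97, CENPE, a kinetochore motor, by -1.51 and SNORA76C by -1.44. Of the cholesterol genes 12 of 24 were lower and 4 higher, HMGCS1 by -0.65 (0.0248, and 0.29 with an estimated correlation). Their androgen-induced genes were not told apart as a list (adjusted p = 0.178). KLK3 differed by 0.03 (95% interval -0.05 to 0.12) and KLK2 by 0.05 (-0.05 to 0.15), whereas FKBP5 differed by -0.41.

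Between olaparib and veliparib, 39 of 43 androgen-induced genes were lower with olaparib and 1 was higher (median -1.10, adjusted p = 4.9e-29, and 0.00457 with an estimated correlation). All 30 mitotic genes were lower (median -0.88, 2.28e-23 and 0.0221), as were 32 of 33 replication genes (median -0.66, 9.29e-19 and 0.00457). KLK2 differed by -4.36, ADAM7 by -4.01, TRPM8 by -3.97, CHRNA2 by -3.95 and MKI67 by -2.01, while ID1 was higher by 2.39, NTS by 2.20, PLD1 by 2.11 and IGFBP3 by 2.09. The lists of homologous recombination, NRF2, the stress responses, the epithelial-mesenchymal transition and fatty acid synthesis were called only with the preset correlation, and their adjusted p with an estimated one was 0.0737, 0.092, 0.092, 0.134 and 0.134. The numbers of genes that were higher and lower were 3222 and 3600 between UPF1069 and olaparib, 3457 and 3324 between UPF1069 and veliparib, and 4229 and 3700 between olaparib and veliparib. Those at least 2-fold apart were 253, 48 and 284. On recovered reads edgeR called 7315 (3735 higher and 3580 lower), 6899 (3493 and 3406) and 8363 (4200 and 4163). In the same order, the fold changes followed GC content with a Spearman's rho of 0.193, 0.649 and 0.345. After correction for GC content and length 7263, 5204 and 8048 genes were called, and 6433, 3867 and 6587 of these had been called before.

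The 3 inhibitor comparisons share the DMSO libraries. UPF1069 and olaparib both raised 715 genes, against 353 for independent lists, and both lowered 1083, against 501, while 397 were called in opposite directions. Their fold changes correlated across genes with r = 0.327, below the 0.499 that simulated unchanged groups gave, but with a covariance of 0.0221 against a simulated 0.0031. For UPF1069 and veliparib r was 0.127 and the covariance 0.0053, with 319 genes raised and 590 lowered by both against 236 and 435 and 675 called in opposite directions. For olaparib and veliparib r was 0.143 and the covariance 0.0114, with 871 and 1154 against 590 and 828 and 1124 in opposite directions, and both r values lay below those of simulated unchanged groups (0.501 and 0.5). In 100 simulations of unchanged groups a mean of at most 0.1 genes was called in the same direction by both. With 2 DMSO libraries the controls could not be split, so part of each excess may come from them. The glycolysis list fell with each compound and was not called between any pair (camera adjusted p = 0.0604, 0.284 and 0.64). The stress-response list fell with UPF1069 and veliparib, was not called between them (0.372), and was not called with olaparib (0.964). For these falls, an effect of the shared DMSO libraries cannot be told apart from the compounds.

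The siRNAs lowered their targets in every library. PARP1 was at 465 ± 19.4 normalised reads per M with siNC, at 5.22 ± 0.632 with siPARP1_A and at 9.02 ± 0.0419 with siPARP1_B (SD, n = 2; log2 fold changes -6.23 and -5.54, adjusted p = 3.03e-27 and 5.06e-26). PARP2 was at 27.4 ± 2.21 with siNC, at 2.81 ± 0.35 with siPARP2_A and at 1.4 ± 0.544 with siPARP2_B (-2.90 and -3.58, adjusted p = 1.23e-14 and 2.41e-17). The siRNAs also moved the other enzyme. PARP1 was at 402 ± 10.2 with siPARP2_A (-0.21, adjusted p = 0.0194, a call that ended without siNC replicate 2, 0.15, or siPARP2_A replicate 2, 0.132) and at 153 ± 11.1 with siPARP2_B (-1.60, adjusted p = 7.66e-16), so that siPARP2_B lowered both. PARP2 was at 21.5 ± 0.83 with siPARP1_A (-0.34, adjusted p = 0.0417) and at 18.9 ± 1.33 with siPARP1_B (-0.51, adjusted p = 0.00429), and the siPARP1_A call ended without any 1 of the siNC, siPARP1_A or siPARP1_B libraries (0.0512 to 0.24), without a filter (0.0692), with a pseudocount of 0.1 (0.102) and with DESeq2 (0.0592), the siPARP1_B call without siNC replicate 1 (0.0612) or siPARP1_B replicate 2 (0.0584).

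**Figure D2:**
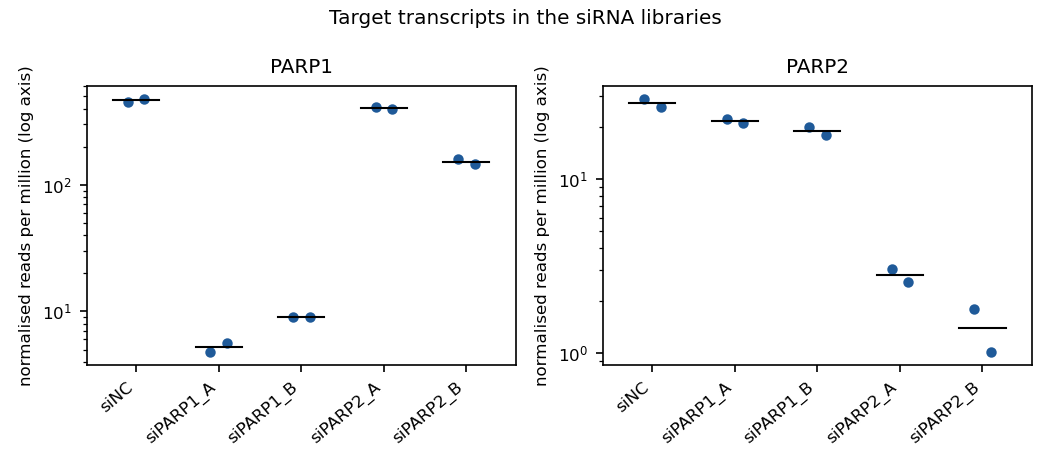
Normalised reads per M of PARP1 and PARP2 in each siRNA library (points, log axis) with group means (bars). PARP1 was at 5.22 and 9.02 with the siPARP1 sequences and at 153 with siPARP2_B against 465 with siNC, and PARP2 at 2.81 and 1.4 with the siPARP2 sequences against 27.4.

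Most luminal epithelial markers fell with both siPARP1 sequences, and the androgen and p53 genes differed between them, but none of these list calls held with an estimated correlation (adjusted p = 0.117 and 0.23 for the luminal markers, and 0.0818 for each difference). Luminal markers fell in 10 of 12 cases with siPARP1_A and in 9 of 12 with siPARP1_B, and 1 rose with each. Androgen-induced genes fell with siPARP1_A in 35 of 45 cases and rose in 5, and with siPARP1_B 12 fell and 13 rose. Of 31 p53 targets, 20 rose and 5 fell with siPARP1_A, and 5 rose and 9 fell with siPARP1_B.

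Past the target, the genes that fell furthest with both sequences were ACPP, which encodes prostatic acid phosphatase, from 102 ± 3.38 to 9.52 ± 0.219 and 22.2 ± 1.77 normalised reads per M (-3.29 and -2.15, adjusted p = 3.97e-20 and 6.82e-16), and COLCA1, from 457.5 ± 3.1 to 85.9 ± 1.79 and 69.7 ± 3.72 (-2.40 and -2.70). AGR2, a secretory disulfide isomerase, changed by -2.57 and -1.66, the interleukin 1 antagonist IL1RN by -2.59 and -1.66, the junction protein gene AMOTL1 by -2.54 and -1.66, and the paralog-rich TUBA1A and the overlapping locus TARP fell too. Keratins KRT8 and KRT18 changed by -1.14 and -1.26 with siPARP1_A and by -0.59 and -0.60 with siPARP1_B. The genes that rose furthest with both were RAB9A, a GTPase of endosomal transport, by 2.01 and 2.04, the transporter SLC35D2 by 2.17 and 1.51, the disaccharidase SI by 1.45 and 1.75, the serine hydroxymethyltransferase SHMT2 by 1.43 and 1.91 and MAL2 by 1.57 and 1.41. The metallothioneins MT1F, MT1G and MT2A rose by 2.36, 1.93 and 2.12 with siPARP1_A, with reads that near-identical family members may share. RAB9A, SLC35D2, MT1G and MT2A were also among the most raised genes with both siPARP2 sequences. Both targets share the siNC libraries, so an effect of siNC on these genes cannot be told apart from the knockdown. TMPRSS2 changed by -1.78 with siPARP1_A and by -1.12 with siPARP1_B, and FKBP5 by -0.94 and -0.26. NCAPD3 changed by -2.54 with siPARP1_A and by 0.33 with siPARP1_B, KLK2 by -1.33 with siPARP1_A while 0.06 with siPARP1_B did not pass, and FOXA1 by -0.90 while 0.12 did not pass. KLK3 changed by -0.99 with siPARP1_A, and its -0.17 with siPARP1_B passed only without siNC replicate 1 (adjusted p = 0.00199) or without siPARP2_B replicate 1 or 2 (0.0331 and 0.0329). CDKN1A changed by 1.25 and -1.29, from 351 ± 25.9 to 835 ± 25.5 and 142 ± 8.3. CYP1A1, a monooxygenase gene, changed by 1.20 and -0.60, and the fall ended without siNC replicate 2 (0.204) or siPARP1_B replicate 1 (0.0576).

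With siPARP1_A, 27 of 33 replication genes fell and 2 rose, with FEN1 at -1.01, and 14 of 30 mitotic genes rose and 1 fell, with CCNB1 at 0.59. The luminal transcription factors fell in 8 of 10 cases and rose in 1, with SPDEF at -0.87. FAS, the death receptor, rose by 2.53 and MDM2, the ligase that restrains p53, by 1.22. With siPARP1_B, 15 of 24 cholesterol genes rose and 5 fell, ACAT2 by 0.84 and SQLE by 0.69. Stress-response genes rose in 13 of 28 cases and fell in 6, with SHMT2 at 1.91 and PHGDH at 1.30, and androgen-repressed genes fell in 10 of 18 cases and rose in 2, led by the UGT2B paralogs, which share reads. In the test of siPARP1_A against siPARP1_B, 36 of 45 androgen-induced genes were lower with A and 5 higher (median -0.83, adjusted p = 7.97e-15), 21 of 31 p53 targets were higher and 3 lower (0.41, 4.91e-05), and 18 of 24 cholesterol genes were lower and 2 higher (-0.36, 4.82e-05). With an estimated correlation these differences had adjusted p = 0.0818, 0.0818 and 0.107.

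With siPARP1_A, camera called the androgen-induced list (median -0.84, adjusted p = 2.61e-12), the luminal markers (-0.71, 6.47e-06), the replication list (-0.51, 6.47e-06), the p53 list (0.43, 0.000153), the luminal transcription factors (-0.59, 0.00319) and the mitotic list (0.28, 0.0064), and with an estimated correlation none was called (0.117, 0.117, 0.153, 0.117, 0.117 and 0.403). With siPARP1_B it called the luminal markers (-0.34, 0.000235), the cholesterol list (0.26, 0.000317), the stress-response list (0.15, 0.00255) and the androgen-repressed list (-0.23, 0.00255), and with an estimated correlation none (0.23, 0.23, 0.217 and 0.291). Adjusted over the list alone, 10 luminal markers fell and 1 rose with siPARP1_A and 9 fell and 1 rose with siPARP1_B, and of the androgen-induced genes 35 fell and 6 rose with siPARP1_A and 14 fell and 14 rose with siPARP1_B. The numbers of genes raised and lowered were 3243 and 3670 with siPARP1_A and 2088 and 3037 with siPARP1_B, of 12701. Both sequences raised 995 genes, against 533 for independent lists, and lowered 1453, against 878, while 894 were called in opposite directions. At least 2-fold, 31 rose and 42 fell with both. The fold changes correlated across genes with r = 0.341, against 0.498 in simulated unchanged groups, and with a covariance of 0.0652 against 0.0067. On recovered reads edgeR called 7274 genes with siPARP1_A (3569 raised and 3705 lowered) and 5126 with siPARP1_B (2479 and 2647). It called 2410 in the same direction with both.

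Both siPARP2 sequences lowered the androgen-induced genes, and most luminal markers fell too, a list call that was lost with an estimated correlation (adjusted p = 0.0725 with siPARP2_A and 0.207 with siPARP2_B). Of 45 androgen-induced genes, 39 fell and 3 rose with siPARP2_A, and 42 fell and 1 rose with siPARP2_B. They differed in the genes of the cell cycle and of interferon: with siPARP2_B all 30 mitotic and all 33 replication genes fell and 26 of 27 interferon-stimulated genes rose, while with siPARP2_A 8 mitotic genes rose and 5 fell and 14 interferon-stimulated genes fell and 2 rose. The p53 targets moved in opposite directions, with 19 of 31 lowered and 5 raised by A, and 22 raised and 9 lowered by B. The p53 and interferon falls with A were lost as lists with an estimated correlation (adjusted p = 0.0596 and 0.113). Because siPARP2_B also lowered PARP1, its effects cannot be assigned to PARP2 alone.

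KLK2 fell from 435 ± 24.5 to 87.9 ± 3.17 and 35.5 ± 5.12 normalised reads per M with siPARP2_A and siPARP2_B (-2.29 and -3.58, adjusted p = 5.12e-18 and 9.48e-23). KLK3 changed by -1.35 and -2.80, FKBP5 by -1.91 and -4.18, and TMPRSS2 by -1.59 and -2.45. FOXA1 changed by -0.72 with siPARP2_A, and its -0.21 with siPARP2_B did not pass without siNC replicate 1 (0.382) or without siPARP2_B replicate 1 (0.589), nor with RLE size factors (0.0502), GC and length correction (0.118) or DESeq2 (0.291). Past the target, the genes that fell furthest with both sequences were KLK2 and SLC26A3, an anion exchanger, at -2.32 and -2.55, NCAPD3, a condensin subunit, at -2.63 and -2.31, the magnesium transporter SLC41A1 at -2.13 and -2.25, the defensin DEFB132, from 140.1 ± 7.32 to 32 ± 2.21 and 19 ± 0.276, the noncoding RNA CCDST at -2.72 and -2.05, and TRIM49D1, which has near-identical copies. The genes that rose furthest with both were RAB9A, from 12.7 ± 0.667 to 47.8 ± 2.58 and 57.4 ± 0.183, SLC35D2, by 1.73 and 1.75, the noncoding RNA LINC01133, by 1.77 and 2.93, the ubiquitin ligase RNF167, from 42.5 ± 0.845 to 132 ± 5.87 and 196.5 ± 13, MAN1A1, by 1.48 and 5.05, FAM177B, by 1.45 and 1.90, and the metallothioneins MT1G and MT2A. SPDEF, an Ets factor of luminal cells, changed by -1.72 with siPARP2_A and by -1.85 with siPARP2_B, and ACPP by -2.05 and -0.62.

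With siPARP2_B, IFIT1, an antiviral RNA-binding protein, rose by 6.75, RSAD2, the antiviral enzyme viperin, by 6.94, OASL by 6.54 and IFIT2 by 6.35, with adjusted p of at most 1.13e-21. NUSAP1, a spindle protein gene, changed by -3.47, CDK1 by -2.97, RRM2 by -3.84 and the repair nuclease EXO1 by -3.19. CDKN1A went from 351 ± 25.9 to 176 ± 14.2 with siPARP2_A and to 1367 ± 31.1 with siPARP2_B (-0.996 and 1.96), GDF15 rose by 2.66 and FAS by 2.29 with siPARP2_B, and BTG2 and TP53INP1 changed by -1.84 and -1.21 with siPARP2_A. The elongase ELOVL5 changed by -1.41 and -2.13. CYP1A1 rose by 0.79 with siPARP2_B, and its -0.18 with siPARP2_A passed only without siNC replicate 1 (-0.48, adjusted p = 0.029). Of the fatty acid list 9 of 15 fell and 2 rose with siPARP2_A, and 12 fell and 2 rose with siPARP2_B. Of the cholesterol list 13 of 24 fell and 3 rose with siPARP2_A, and of the poly(ADP-ribose) polymerase family 9 of 17 fell and 2 rose, with PARP14 at -1.54 and PARP9 at -0.81. PARP2, the target itself, belongs to this family. NRF2 targets rose in 11 of 16 cases and fell in 2 with siPARP2_B, HMOX1 by 2.04. Of the epithelial-mesenchymal list 4 of 8 fell with siPARP2_A, FN1 by -1.30.

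**Figure D3:**
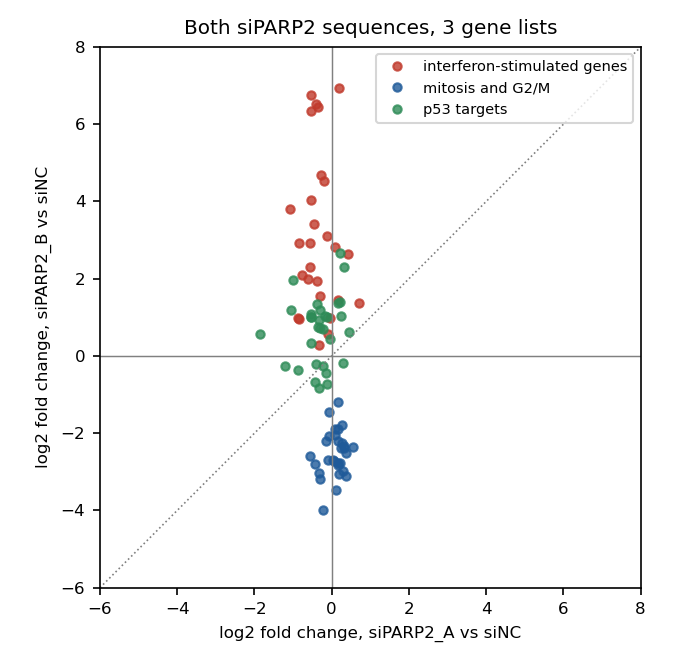
Log2 fold changes against siNC with siPARP2_B (vertical axis) and siPARP2_A (horizontal axis), where each point is a gene of the interferon, mitotic or p53 list. The interferon genes have medians of 2.81 with B and -0.38 with A, the mitotic genes -2.55 and 0.15, and the p53 targets 0.74 and -0.30.

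The lists whose camera call with siPARP2_A held with an estimated correlation were the androgen-induced genes (median -1.11, adjusted p = 8.55e-28, then 0.0427) and the luminal transcription factors (8 of 10 lowered, -0.66, 1.77e-05, then 0.0427). The luminal markers (11 of 12 lowered and 1 raised, -0.77, 2.48e-07), p53 targets (-0.30, 0.000567), fatty acid (-0.45, 0.00137), cholesterol (-0.20, 0.0072), interferon (-0.38, 0.00757), epithelial-mesenchymal (-0.69, 0.00788) and polymerase family lists (-0.19, 0.0424) were lost, with adjusted p = 0.0725, 0.0596, 0.106, 0.193, 0.113, 0.106 and 0.26, and the polymerase call also ended without siNC replicate 1 (0.0803) and after GC and length correction (0.0683). With siPARP2_B the calls of the mitotic (-2.55, 3.33e-20), interferon (2.81, 1.65e-19), androgen-induced (-1.47, 3.27e-18), replication (-1.41, 3.23e-16), homologous recombination (26 of 32 lowered and 2 raised, -0.99, 2.39e-07), fatty acid (-1.04, 6e-05) and p53 lists (0.74, 6.58e-05) held, with 0.0262, 0.00723, 0.0285, 0.0262, 0.0161, 0.0478 and 0.0262. The luminal markers (9 of 12 lowered and 2 raised, 0.00635), the luminal transcription factors (7 of 10 lowered and 3 raised, 0.0232) and NRF2 targets (0.0232) were lost, with 0.207, 0.112 and 0.237, and the NRF2 call ended without siPARP2_B replicate 2 (0.0627). Adjusted over the list alone, 39 androgen-induced genes fell and 3 rose with A, 42 fell and 1 rose with B, and 26 interferon-stimulated genes rose with B.

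In the test of siPARP2_A against siPARP2_B, all 27 interferon-stimulated genes were lower with A (median -2.88, adjusted p = 2.39e-21, and 0.0058 with an estimated correlation), all 30 mitotic genes higher (2.67, 1.72e-21 and 0.023), and 23 of 31 p53 targets lower and 5 higher (-1.09, 1.04e-08 and 0.00893), while the androgen-induced list was not called (0.31, 0.0529). The numbers of genes raised and lowered were 3111 and 3166 with siPARP2_A and 3924 and 4466 with siPARP2_B, and edgeR called 6437 and 9008 on recovered reads. Both sequences raised 1511 genes, against 961 for independent lists, and lowered 1770, against 1113, while 1376 were called in opposite directions. At least 2-fold, 48 rose and 134 fell with both. Their fold changes correlated across genes with r = 0.303, against 0.498 in simulated unchanged groups, with a covariance of 0.0964 against 0.0067. Across targets, r between a siPARP1 and a siPARP2 sequence was 0.459 for A with A, 0.107 for B with B, 0.298 for siPARP1_A with siPARP2_B and 0.341 for siPARP1_B with siPARP2_A, each below the 0.498 to 0.5 of simulated unchanged groups. Their covariances were 0.1022, 0.0293, 0.118 and 0.0523 against 0.0067. Unchanged groups have such an r from the shared siNC libraries alone, so a lower r does not show less agreement. Genes called in the same direction numbered 3215, 2171, 3389 and 2199, and those called in opposite directions 839, 1531, 1641 and 844. In the same order, 1464, 841, 1493 and 915 genes were raised by both, against 794, 645, 1002 and 511 for independent lists. Both lowered 1751, 1330, 1896 and 1284, against 915, 1068, 1290 and 757. An excess over independent lists was thus not particular to the sequences of 1 target. All 4 sequences raised 352 genes and lowered 515, all against the same siNC libraries. With 2 siNC libraries these controls could not be split either, and what siNC itself does to the cells was not measured.

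The comparison of the siPARP2 with the siPARP1 sequences asks which transcripts differ between the targets, and it takes the libraries of a sequence as replicates. With 1 value per sequence limma called 0 genes, and the mitotic and interferon differences rest on siPARP2_B, as given below. Androgen-induced genes were lower with siPARP2 in 41 of 45 cases and higher in 1, all 30 mitotic genes were lower, and 24 of 27 interferon-stimulated genes were higher and 1 lower. FKBP5 differed by -2.44, KLK2 by -2.30, KLK3 by -1.50 and SPDEF by -1.20, while FOXA1 (-0.08) passed only without siPARP2_B replicate 2 (-0.16, adjusted p = 0.0187). Among genes whose libraries did not overlap between the targets, the largest differences besides the targets were those of MAN1A1 at 3.57, SIPA1L2 at 2.65, the receptor TNFRSF12A at 2.32 and PPP1R14C at 2.26, with TUBA1A, higher as well, open to reads of its paralogs, and in the other direction the kinase MAK at -2.48, the transhydrogenase NNT at -2.41 and CCDC141 at -2.31. TOP2A differed by -2.28, IFIT1 by 3.17, ISG15 by 2.16 and ELOVL5 by -1.27.

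The median differences were -0.89 for the androgen-induced list (camera adjusted p = 5.3e-20), -1.33 for the mitotic list (3.81e-20), 1.31 for the interferon list (4.77e-12), -0.68 for the fatty acid list (14 of 15 lower and 1 higher, 9.54e-08) and -0.45 for the homologous recombination list (20 of 32 lower and 5 higher, 0.00147), with adjusted p = 0.0344, 0.0344, 0.024, 0.0344 and 0.0429 with an estimated correlation. The replication (25 of 33 lower and 1 higher, 7.39e-07), cholesterol (18 of 24 lower and 3 higher, 0.000442) and luminal factor lists (6 of 10 lower and 3 higher, 0.0363) were lost, with 0.108, 0.114 and 0.124. Adjusted over the list alone, 41 androgen-induced and 30 mitotic genes were lower and 1 androgen-induced gene was higher. The interferon, mitotic, homologous recombination and replication differences rest on siPARP2_B, since against siNC siPARP2_A changed none of these lists in that direction (medians -0.38, 0.155, 0.16 and 0.11). The androgen-induced list had medians against siNC of -0.84 with siPARP1_A, 0.004 with siPARP1_B, -1.11 with siPARP2_A and -1.47 with siPARP2_B, so its difference varies with the sequences compared. Of 12701 genes, 4234 were higher and 4090 lower, 545 of them at least 2-fold, and edgeR called 8767. These counts and the list tests above take the libraries of a sequence as replicates, and no list was tested with 1 value per sequence. With 1 value per sequence limma called 0 genes. An unadjusted p under 0.05 was found for 520 of 12701 genes, no more than unchanged genes would give. PARP1 and PARP2, which differed by 4.98 and -2.82, were not called either. With 2 residual degrees of freedom the test missed the targets themselves, so it cannot show that other genes do not differ. The edgeR and DESeq2 tests were run on libraries only.

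**Figure D4:**
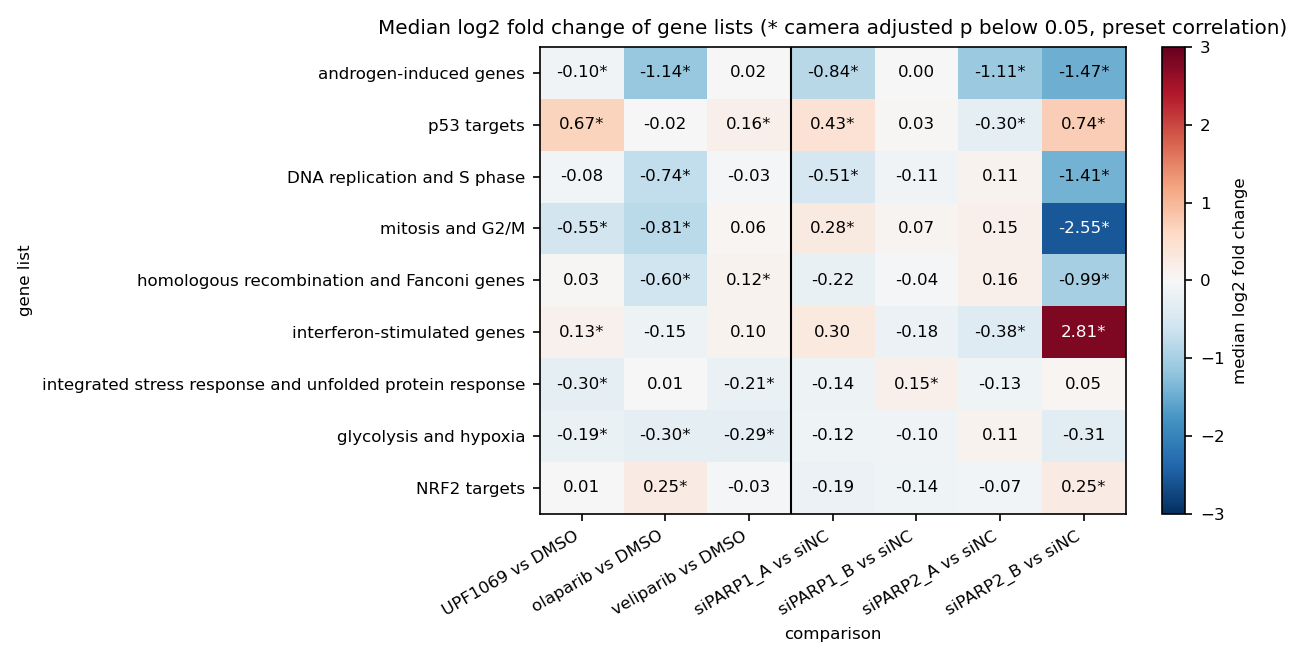
Median log2 fold change of 9 gene lists (vertical axis) in the 3 inhibitor comparisons with DMSO and the 4 siRNA comparisons with siNC (horizontal axis), printed in each cell and coloured from -3 to 3, with a star where the camera adjusted p with preset correlation was below 0.05. The androgen-induced genes have medians of -1.14 with olaparib, -1.11 with siPARP2_A and -1.47 with siPARP2_B.

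Genes changed by a compound were followed into the knockdown libraries, which have control libraries of their own. The genes that olaparib lowered were lower after PARP2 knockdown as well. As a set of 3353 genes they had a median log2 fold change of -0.16 over both siPARP2 sequences (camera adjusted p = 2.03e-05 over the 12 sets tested, and 0.00688 with an estimated correlation) and of -0.04 over the siPARP1 sequences (adjusted p = 0.575). The difference between the knockdowns had an adjusted p = 6.66e-05, and 0.00512 with an estimated correlation, a test that also takes the libraries of a sequence as replicates. With siPARP2_B alone the median was -0.26 (adjusted p = 5.45e-07), and with siPARP2_A alone it was -0.03 and not called (0.45), so the call of the full set rests on siPARP2_B. Of the 165 genes that olaparib lowered at least 2-fold, the mean of the siPARP2 sequences lowered 131 and raised 17, siPARP2_A 119 and 13, and siPARP2_B 120 and 27, while the mean of the siPARP1 sequences lowered 79 and raised 38, siPARP1_A 95 and 32, and siPARP1_B 52 and 45. This smaller set was called with siPARP2 (median -0.855, adjusted p = 1.1e-20) and with siPARP1 (-0.22, 0.00354), and its difference between the knockdowns was not tested.

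Genes that olaparib raised were not called as a set in either knockdown (siPARP2 median 0.04, adjusted p = 0.152, and siPARP1 adjusted p = 0.42), although without DMSO replicate 2 the siPARP2 median of 0.05 passed (adjusted p = 0.0476). The difference of this set between the knockdowns (median 0.09) was called by camera (adjusted p = 0.00202), a call lost with an estimated correlation (0.171). The genes that UPF1069 raised or lowered were not called with siPARP2 (adjusted p = 0.732 and 0.401) or with siPARP1 (0.364 and 0.912), nor were those of veliparib (0.434 and 0.434 with siPARP2, 0.401 and 0.732 with siPARP1). The full UPF1069-raised set had medians of -0.04 with siPARP2 and -0.07 with siPARP1, but its 21 genes raised at least 2-fold were called in the other direction (0.43, adjusted p = 0.00606, and 0.28, 0.00798), and the 65 genes that olaparib raised at least 2-fold were called with siPARP2 (0.36, 2.1e-05). The set that UPF1069 lowered passed with siPARP2 without DMSO replicate 2 (median -0.12, adjusted p = 0.0235) and without UPF1069 replicate 1 (-0.13, 0.0256). Across 12275 genes, which are not independent replicates, the fold changes of olaparib and of the siPARP2 mean had r = 0.323 and a Spearman's rho of 0.221, against 0.029 and 0.004 for siPARP1. By sequence, r and rho were 0.189 and 0.058 with siPARP2_A, 0.31 and 0.258 with siPARP2_B, 0.068 and 0.032 with siPARP1_A, and -0.039 and -0.04 with siPARP1_B, so the contrast by rank rests on siPARP2_B. For UPF1069 r was 0.097 with siPARP2, from -0.086 with siPARP2_A and 0.174 with siPARP2_B, and -0.048 with siPARP1, and for veliparib 0.001 and -0.008.

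Few genes of other cell types were measured. Of the neuroendocrine, basal, stromal, and immune and endothelial marker lists 4, 3, 3 and 1 members passed the filter, too few for a test. With siPARP2_B 2 neuroendocrine markers rose and 1 fell, 2 basal and 3 stromal markers rose and the 1 immune or endothelial marker rose. With siPARP1_A 1 neuroendocrine marker rose and 1 fell, 1 basal and 2 stromal markers rose and the immune or endothelial marker rose. With siPARP1_B 2 neuroendocrine markers rose, 1 basal marker fell, 1 stromal marker rose and 1 fell, and the immune or endothelial marker fell. With siPARP2_A 1 neuroendocrine marker rose and 1 fell and 1 basal marker rose. With olaparib 1 neuroendocrine marker rose and 2 fell, and 2 basal markers, 1 stromal marker and the immune or endothelial marker fell. With UPF1069 1 neuroendocrine and 1 stromal marker rose and 1 basal marker rose and 1 fell, and with veliparib 3 neuroendocrine markers and 1 stromal marker fell and 1 basal marker rose. In each called list the median, the mean and the test had the same sign. Among lists not called they differed for the aryl hydrocarbon receptor, NRF2 and epithelial-mesenchymal lists with UPF1069, for the luminal factor, polymerase family and stress-response lists with olaparib, and for the androgen-induced, androgen-repressed, NF-kB, cholesterol and fatty acid lists with veliparib. They also differed for the fatty acid and NRF2 lists with siPARP1_A, the p53 and NF-kB lists with siPARP1_B, the glycolysis list with siPARP2_A, and the polymerase family and epithelial-mesenchymal lists with siPARP2_B. Between groups they differed for the luminal factor list of UPF1069 against olaparib, the luminal factor, polymerase family and glycolysis lists of olaparib against veliparib, and the polymerase family, p53, base excision, NF-kB and glycolysis lists of siPARP2 against siPARP1. They differed too for the glycolysis and epithelial-mesenchymal lists between the siPARP1 sequences and for the cholesterol list between the siPARP2 sequences.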

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

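The tests of histone genes and of other splits of the libraries were fixed before their results were seen, and all other tests of explanations here were chosen afterwards.

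Differences between the sequences of a target are given here where each was tested and passed. For a gene called in opposite directions against the same siNC libraries, the difference is larger than either change. The test of that difference therefore adds no support of its own. Of the genes called with both siPARP1 sequences, 894 went in opposite directions. CDKN1A changed by 1.25 with siPARP1_A and by -1.29 with siPARP1_B, a difference of 2.54. For CYP1A1 the changes were 1.20 and -0.60, a difference of 1.801. The CYP1A1 fall is not firm, since it ended without siNC replicate 2 (adjusted p = 0.204) or siPARP1_B replicate 1 (0.0576).

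With the siPARP2 sequences 1376 genes went in opposite directions. CDKN1A changed by -0.996 with siPARP2_A and by 1.96 with siPARP2_B, a difference of -2.96. The p53 list had medians of -0.30 and 0.74, and the median of its differences was -1.09. The interferon list had medians of -0.38 and 2.81, and the median of its differences was -2.88.

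The interferon rise and mitotic fall with siPARP2_B were weighed first. Loss of PARP1 by itself is argued against, since the higher of the interferon medians of the siPARP1 sequences, which lowered PARP1 further, was 0.30. Loss of PARP2 common to both sequences is argued against by the median of -0.38 with siPARP2_A. The median of 2.81 with siPARP2_B alone is what a response to that RNA duplex would give, but a combined loss of PARP1 and PARP2 occurs in the same libraries, so these could not be told apart. The biological explanation therefore stays untested.

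The 5387 mostly small changes with veliparib were weighed second. A trend with GC content may contribute, since the fold changes followed GC content with a Spearman's rho of -0.698, against 0.116 and -0.112 for the other compounds, and the veliparib replicates also differed from each other along it (0.508). As the whole cause, the trend with GC content and length per gene is argued against, because 2642 genes were called in the same direction before and after correction. The correction used 1 value of each per gene, and the veliparib replicates were the noisiest of the inhibitor groups (chi-square per gene 5.64). Other technical differences between libraries could remain after it and were not tested. Carry-over of RNA without poly(A) tails could not be told apart from other causes: histone genes had a median of 0.071 (camera adjusted p = 0.134), while 5 structural RNAs rose at least 2-fold. A response to veliparib itself stays open and untested.

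The fall of androgen-induced genes with olaparib and the rise of p53 targets with UPF1069 were weighed last. Fewer dividing cells as the cause of the p53 rise could not be settled. Mitotic genes fell at least as far with olaparib (median -0.81, against -0.55 with UPF1069). Yet the p53 list was higher with UPF1069 than with olaparib (median difference 0.892). So with olaparib such a fall came without a rise of the p53 list (median -0.02). But the replication list fell with olaparib (median -0.74) and was not called with UPF1069, so the loss of dividing cells need not have been alike. For the same reason, fewer dividing cells as the cause of the androgen fall could not be told apart from other causes. With UPF1069 the androgen-induced genes had a median of -0.099 while mitotic genes fell. An exchange of the UPF1069 and olaparib labels could not be told apart from correct labels: androgen-induced genes fell further with siPARP2 than with siPARP1 (median difference -0.89), which an exchange predicts and correct labels allow, and no measured transcript identifies a compound. Different actions of the compounds at 10 uM stay open and untested.

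For siPARP2 against siPARP1, 1 of the 35 splits of the 8 siRNA libraries into groups of 4, the real one, called as many as 909 genes in a fit of 2 groups of 4, and the highest other split called 753. The 3 splits that keep the libraries of each sequence together, the real one included, were the ones that called genes, but a split that parts them puts the differences between sequences into the residual variance. With libraries tied by sequence, 3 splits are too few for a share under 0.05.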

How the results depend on the processing

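Chosen after the data had been seen were edgeR on recovered reads, the fold threshold on genes, the GC and length correction, 1 value per sequence, the comparison without siPARP2_B, single sequences and the mean of both sequences, and the other alternatives were planned. For the counts of genes and the inhibitor-changed sets, 485 values under an alternative kept their direction and their side of the threshold, or lay within 1.5 times the count, while 12 rose past that limit, 22 fell below it and 2 reversed, both of them sets described below. For named genes and lists the numbers were 4525, 7 and 118. None of those reversed in its test, but without UPF1069 replicate 2 the median of the androgen-repressed list with UPF1069 went from 0.08 to -0.01 and its call ended (adjusted p = 0.079). Of 97 list calls, 58 were lost with an estimated correlation. That setting also lowers the degrees of freedom, and some calls were lost where the estimate lay below the preset 0.01. With olaparib, the epithelial-mesenchymal list had an estimate of -0.035 (camera adjusted p = 0.00206, then 0.0789). These losses therefore do not by themselves show correlated members.

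The UPF1069 count of 3245 was 5041 with only the groups compared, 2109 with DESeq2, and between 1575 and 4914 without 1 library. It was 1648 and 1770 without DMSO replicates 1 and 2, 1660 and 1575 without UPF1069 replicates 1 and 2, and 4914 and 4910 without veliparib replicates 1 and 2. The share raised was 42.3% with limma and 52.3% with edgeR. The inhibitor groups share 1 estimate of spread, to which the noisier veliparib replicates (chi-square per gene 5.64) contribute. With only the groups compared, the veliparib count was 4323. The veliparib count of 5387 was 3273 after the GC and length correction and 3560 (without DMSO replicate 1) to 6780 (without veliparib replicate 2) without 1 library. The cause was not tested.

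An absolute log2 fold change of at least 1 is stricter by construction. It left 35 genes for UPF1069, 248 for olaparib, 12 for veliparib, 253, 48 and 284 for UPF1069 against olaparib, UPF1069 against veliparib and olaparib against veliparib, 785 and 228 for siPARP1_A and siPARP1_B, 384 and 1677 for siPARP2_A and siPARP2_B, 545 for siPARP2 against siPARP1, and 73 and 182 with both siPARP1 and both siPARP2 sequences. The mean of both sequences, which does not need each to pass, gave 5925 and 7441. With 1 value per siRNA sequence and 2 residual degrees of freedom, limma called 0 genes for siPARP2 against siPARP1. The 520 genes at an unadjusted p under 0.05 are no more than unchanged genes would give. PARP1 and PARP2 were not called either, so this test cannot show that other genes do not differ. On libraries edgeR called 8767 and DESeq2 7381, and without siPARP2_B 6889 genes were called.

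Among the inhibitor-changed sets, those at an absolute log2 fold change of at least 1 gave calls that the full sets did not. The UPF1069-raised set of 21 genes had a median of 0.28 (0.283) with siPARP1 (adjusted p = 0.00798) and 0.43 (0.429) with siPARP2 (0.00606), where the full set had -0.07 and -0.04 and so the other sign. The olaparib-lowered set of 165 genes had -0.22 with siPARP1 (0.00354), and the olaparib-raised set of 65 genes 0.36 (0.357) with siPARP2 (2.1e-05). With siPARP2_B alone the UPF1069-lowered set had -0.13 (-0.127, 0.0456) and the olaparib-raised set 0.09 (0.093, 0.0224), and with siPARP2_A alone the olaparib-lowered set had -0.03 (-0.031, 0.45). Without 1 library the UPF1069-lowered set ran from -0.13 (-0.133, without UPF1069 replicate 1) to -0.04 (without veliparib replicate 1) and the olaparib-raised set from 0.02 (0.024, without siNC replicate 2) to 0.05 (0.051, without olaparib replicate 2) with siPARP2. The first passed without DMSO replicate 2 (adjusted p = 0.0235) or UPF1069 replicate 1 (0.0256), the second without DMSO replicate 2 (0.0476). The cause was not tested.

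These set results use p values adjusted over the sets, a choice made after the unadjusted ones were seen. Unadjusted, 267 set values would have stayed on their side, 9 risen past the threshold, 4 fallen below it and 2 reversed, against 272, 7, 1 and 2 adjusted, and the olaparib-raised set with siPARP2 would have passed (0.0253 against 0.152).

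The labels give the libraries of each group the same replicate numbers, and nothing says what they share. Deviations of same-numbered libraries correlated between -0.06 and 0.03 in the inhibitor table and between -0.141 and 0.115 in the siRNA table. With a replicate block the counts were 3011 for UPF1069, 6885 for olaparib, 5224 for veliparib, 8324 for siPARP2_B and 8260 for siPARP2 against siPARP1. The block ended the call of the base excision list between UPF1069 and olaparib (adjusted p = 0.0503) and no other call of a named gene, list or set.

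The direct tests between the sequences of a target were repeated only after the GC and length correction and, for lists, with an estimated correlation and fry. Without 1 library, the lone library of its group was assumed to vary like the other groups. Depth and noise between libraries, which no test separates, limit small changes. Of simulated log2 changes of 0.25, 22% were recovered in the siRNA table and 54% in the inhibitor table. The simulation changed far fewer genes than were called here, so these shares need not hold for the data.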

Other observations

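The test of histone genes was fixed before its result was seen, and the genes below were chosen afterwards.

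RAB9A, MT1G, MT2A and SLC35D2 were high in every library with an siRNA against either target. RAB9A was at 12.7 normalised reads per M with siNC, between 46 and 57.5 in the knockdown libraries, and at 32.6 CPM with DMSO in the inhibitor table. MT1G was at 10.8 with siNC, between 43 and 75.05 in the knockdown libraries, and at 19.1 with DMSO. MT2A was at 28.5, between 78.5 and 158, and at 64.4, and SLC35D2 at 10.1, between 29 and 50.5, and at 20.5. The siNC libraries differed widely in MT2A (SD 14.8). The tables were normalised apart, so the DMSO values are given as levels only, and metallothionein reads are open to near-identical family members.

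Of 20 histone cluster genes, 9 fell with UPF1069 (median log2 fold change -0.25, camera adjusted p = 3.49e-06), 11 rose and 3 fell with olaparib (0.26, 0.0198), and 3 rose and 1 fell with veliparib (0.07, 0.134).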
